A study of Mus musculus with 3 samples.

How the data were processed

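The data are counts of unique molecular identifiers (UMIs) per gene and cell barcode from droplet single-cell RNA sequencing, for 3 libraries of sorted cells from a pool of 3 mouse embryos at embryonic day 11.5. The count matrices were deposited by the authors as filtered matrices, 1 per library, with 27998 gene IDs each. Per the submitters' processing notes, Cell Ranger 3.0.4, Seurat 4.0.0 and the mm10 genome were used, and the notes give neither role nor order for them. The gene annotation used for counting and whether counting used strand are not given in the sources used here. Without strand, reads of antisense or overlapping genes, such as Tsix and Xist, cannot be told apart, and reads shared by near-identical genes are uncertain. Of the gene IDs, 27645 matched the GENCODE M21 annotation of mm10, from which positions were taken. Groups were taken from the labels, with 1 library of 6871768 to 19725719 UMIs each.

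All counts were used as deposited. Cells with at least 1000 genes detected and at most 10% mitochondrial UMIs were kept, which left out 52, 79 and 39 barcodes of the AGM pre-HSC/endothelial, AGM progenitor and fetal liver progenitor libraries. The kept cells held 6749044, 14970816 and 19672102 UMIs, with medians of 5015, 4948 and 5142.5 genes per cell. Scrublet, run within each library with 20 components and 0.8% doublets assumed per 1000 cells, called 13 doublets, which were left in. Counts per cell were scaled to 10000, log-transformed and reduced to 2000 variable genes and 30 principal components. Leiden clustering of the graph of 15 neighbours at resolution 1.0 then gave 13 clusters, without batch integration. Cluster genes were ranked by fold among genes detected in at least 25% of the cluster's cells, and a cluster took the name of the class with the most markers among the top 50, if at least 3 were there, no class tied with it and none had more markers in the top 10. Markers covered 14 classes, namely endothelial, stem and multipotent progenitor, granulocyte-monocyte progenitor, macrophage-monocyte, erythroid, megakaryocyte, mast-basophil-eosinophil and lymphoid cells, and hepatoblast, mesenchyme, epithelium, primordial germ cell, neural crest and neuron, and muscle.

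With 1 library per group no test was made. Counts were summed over cells, for all cells and for each class with at least 20 cells in both libraries, and divided by the total to give counts per 1000000 (CPM), which gave 3 comparisons of libraries and 5 of classes. Levels have exact Poisson intervals, shares exact Clopper-Pearson intervals and ratios exact intervals from the binomial split of the counts, all at 95% and all for counting error only. A count under 3 was set to 3 for list medians and for ranking, a ratio against 0 UMIs is a lower bound against 3 UMIs, and a ratio against 1 to 3 UMIs is given with its interval. For genes, those with at least 20 UMIs over both libraries were measured.

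The 35 gene lists, the cluster markers, the filters and the rule for naming genes were fixed before the data were examined. The rule takes, in each comparison of libraries, the 10 highest and 10 lowest log2 ratios among genes with at least 100 UMIs that are detected in at least 10% of the cells of the higher library. Within a class it takes the 8 highest and 8 lowest with at least 50 UMIs, and from each described list the 4 members with the largest log2 ratio of either sign. Mitochondrial, ribosomal protein, globin, Xist, Y-linked, predicted and unnamed genes and sort markers stay out of the ranking, the sort markers are always named, and globins are given as lists. Within a class the text departs from this and names only sort markers whose ratio has an interval that excludes 1. A share of 0 cells is given the limit of 3 cells of the total. Class markers and leading genes of a class's own clusters are not counted as results within it. Which lists are described with members was chosen after their values were seen.

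The lists are pan-endothelial, arterial endothelial, venous endothelial, hematopoietic transcription factors, HSC-associated, fetal Lin28b program, granulocyte-monocyte progenitor, macrophage-monocyte, erythroid, megakaryocyte, mast-basophil-eosinophil, lymphoid, embryonic globins, adult globins, S phase, G2-M phase, quiescence and CDK inhibitors, Notch pathway, BMP-TGFb pathway, interferon and inflammatory, shear-responsive, glycolysis, oxidative phosphorylation, cholesterol synthesis, heme synthesis and iron, adhesion and homing, Hox genes, dissociation immediate-early, sort markers and the 6 lists of other cell types. Sort markers are given singly and their median is not used. Lists share genes, for example Csf1r in the granulocyte-monocyte and macrophage lists. Ltbp4, Gpr56, Ahsp, Pimreg, Itgam, Jaml and Stella had no entry under these symbols and were not used. A list median has an order-statistic interval over its members, the whole range under 6 members. Its percentile among 10000 random lists of the same size, drawn within 20 bins of mean expression with seed 1, describes these libraries and is no p-value.

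Cell cycle shares were taken after thinning each cell to 5000 UMIs and leaving out shallower cells. Alternatives chosen at the same time as the lists were median-of-ratios scaling, scaling without globin, mitochondrial and ribosomal protein genes, the mean of per-cell CPM, all deposited barcodes, at least 2000 genes with at most 5% mitochondrial UMIs, doublets left out, the 5% of cells with the most UMIs left out, a minimum of 1 UMI, and cells thinned to 5000 UMIs. For clusters they were resolutions 0.6 and 1.5, 3000 variable genes with 20 components and cell cycle genes left out, for cell cycle shares own depth and 10000 UMIs, and for medians a pseudocount of 0.5. Alternatives chosen after seeing the data left out the cell with germ cell markers, cells with over 50 embryonic globin UMIs, cells with Xist and Y-linked UMIs, cells with at least 4 mesenchyme markers and cells with over 10 eosinophil granule UMIs.

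Ratios and lists were tested on counts simulated from real means and totals, which cannot cover UMIs clumped in few cells or co-regulated lists. Known changes of 2-fold, 4-fold and 8-fold in 68, 66 and 66 genes all had the right direction. The 95% interval held the true value for 98.5%, 97.0% and 98.5% of the changed genes in AGM pre-HSC/endothelial against AGM progenitor, 92.7%, 97.0% and 92.4% in fetal liver against AGM progenitor, and 100%, 97.0% and 87.9% in AGM pre-HSC/endothelial against fetal liver. For unchanged genes it did so for 95.9% of 11405, 95.5% of 11400 and 95.8% of 11237. A requirement of over 90% coverage per group of changed genes failed at 87.9% and was dropped. Of 50 random unchanged lists per comparison, 49, 49 and 47 had percentiles between 2.5 and 97.5. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9.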

Results

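Blood-forming cells of the mouse embryo were profiled by droplet single-cell RNA sequencing (10x Chromium 3' v3), in which each captured mRNA is counted once by its unique molecular identifier (UMI). The cells came from a pool of 3 Bl6 embryos at E11.5. The aorta-gonad-mesonephros region (AGM) is where the first hematopoietic stem cells (HSC) arise from endothelium, and the fetal liver is the organ that blood progenitors then colonise. Each of the 3 sorted groups was 1 library, and lineage markers were Ter119, Gr1, CD19 and CD3. The AGM pre-HSC/endothelial library held lineage-negative cKit+ CD45lo/mid CD31+ VE-cadherin+ cells, and the AGM progenitor library held lineage-negative cKit+ CD45+ cells. The fetal liver progenitor library mixed separately sorted cKit+/high CD45+ cells that were either CD41- or CD41high, at a ratio not given in the labels. The deposited tables held 269, 578 and 577 cell barcodes with 6871768, 15149609 and 19725719 UMIs in that order. After filtering, 217, 499 and 538 cells remained, with medians of 29840, 30644 and 37617 UMIs per cell. There were no replicates, so no difference was tested. Brackets of levels, shares and ratios are 95% intervals that cover counting error only. Brackets of list medians are order-statistic intervals over the members of the list, and the whole range under 6 measured members. The words "higher" and "lower" describe these libraries. Ratios are between counts per 1000000 UMIs (CPM) summed over cells. A ratio against 0 UMIs is a lower bound set against a floor of 3 UMIs.

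The RNA of the surface markers used for sorting differed between the libraries, in the order AGM pre-HSC/endothelial, AGM progenitor and fetal liver. Kit, the stem cell factor receptor, stood at 70.4 [64.2, 77.0], 55.9 [52.2, 59.8] and 78.8 [75, 82.9] CPM. Ptprc, which encodes CD45, stood at 7.56 [5.63, 9.94], 81.6 [77.1, 86.3] and 11 [9.56, 12.5] CPM, so the fetal liver cells gated as CD45+ held less of it than the AGM progenitors. Cdh5, which encodes VE-cadherin, stood at 108 [100, 116], 2.54 [1.80, 3.48] and 0.305 [0.112, 0.664] CPM, and Pecam1, which encodes CD31, at 63.4 [57.5, 69.7], 20.2 [18.0, 22.7] and 10.5 [9.09, 12.0] CPM. Itga2b, which encodes CD41, stood at 28.0 [24.2, 32.3], 17.7 [15.6, 20] and 26.4 [24.2, 28.8] CPM. Gypa, which encodes the glycophorin with which the Ter119 antigen is associated, stood at 2.67 [1.58, 4.22], 5.94 [4.77, 7.32] and 28.4 [26.1, 30.8] CPM. The other lineage genes were rare: Ly6g and Cd3e had 0 UMIs in every library, Ly6c1 had 4, 0 and 0, Ly6c2 2, 3 and 0, Cd19 0, 2 and 0, Cd3d 0, 1 and 0, and Cd3g 0, 15 and 32. The floor of 3 UMIs equals 0.445, 0.20 and 0.153 CPM. In the mm10 annotation of GENCODE M21 these protein-coding genes are Kit (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722), Ptprc (ENSMUSG00000026395, chromosome 1, 138062861 to 138175708), Cdh5 (ENSMUSG00000031871, chromosome 8, 104101625 to 104144511), Pecam1 (ENSMUSG00000020717, chromosome 11, 106654217 to 106750628) and Itga2b (ENSMUSG00000034664, chromosome 11, 102453297 to 102470122).

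Clustering of the 1254 cells gave 13 clusters, of which 12 were named after fixed markers. Endothelial-like cells (cluster 1, with Cldn5, Emcn and Kdr) formed 97 of 217 cells (44.7% [38.0, 51.6]) of the AGM pre-HSC/endothelial library and 0 cells of the AGM progenitor and fetal liver libraries, which allows shares of up to 0.601% and 0.558%. Because that cluster came from 1 library, it cannot be separated from the library itself. Stem and multipotent progenitor-like cells (cluster 4, with Hlf, Hoxa9 and Mycn) formed 51 of 217 cells (23.5% [18.0, 29.7]) of the AGM pre-HSC/endothelial library, 25 of 499 cells (5.01% [3.27, 7.31]) of the AGM progenitor library and 16 of 538 cells (2.97% [1.71, 4.78]) of the fetal liver library, or 37.8%, 9.02% and 6.32% with 3000 variable genes and 20 components. Megakaryocyte-like cells (clusters 0 and 2, with Gp1bb, Gp5 and Treml1) formed 47 of 217 cells (21.7% [16.4, 27.7]), 35 of 499 cells (7.01% [4.93, 9.62]) and 124 of 538 cells (23.0% [19.6, 26.8]) in the same order. How much of the CD41high fraction was mixed into the fetal liver library is unknown, and under other settings the 3 shares went down to 6.32%, 0.173% and 4.51%, while the AGM progenitor share reached 11.2%.

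Myeloid cells made up most of the AGM progenitor library. Macrophage-monocyte-like cells (clusters 7, 9 and 10, with C1qa, C1qb and C1qc) formed 217 of 499 cells (43.5% [39.1, 48]) of it and 4 of 538 cells (0.743% [0.203, 1.89]) of the fetal liver library. Granulocyte-monocyte progenitor-like cells (clusters 3 and 11, with Mpo, Prtn3 and Serpinb1a) formed 108 of 499 cells (21.6% [18.1, 25.5]) of the AGM progenitor library, 45 of 538 cells (8.36% [6.17, 11]) of the fetal liver library and 14 of 217 cells (6.45% [3.57, 10.6]) of the AGM pre-HSC/endothelial library. Under other settings these ran from 14.8% to 26.3%, 3.72% to 9.48% and 0% to 11.7%. Lymphoid-like cells (cluster 12) formed 53 of 499 cells (10.6% [8.06, 13.7]) of the AGM progenitor library and 14 of 538 cells (2.60% [1.43, 4.33]) of the fetal liver library. That name rests on Il7r, Lsp1 and Ltb, while the macrophage-monocyte markers Ccr2 and Irf8 also stood among the 10 leading genes of the cluster. Cluster 8, led by Ifitm1, Rnase12 and Hdc, stayed unnamed and held 42 of 499 cells (8.42% [6.13, 11.2]) and 13 of 538 cells (2.42% [1.29, 4.10]) in the same order. Erythroid-like cells (clusters 5 and 6, with Klf1, Epor and Ermap) were 322 of 538 cells (59.9% [55.6, 64.0]) of the fetal liver library, against 19 of 499 cells (3.81% [2.31, 5.88]) of the AGM progenitor library and 8 of 217 cells (3.69% [1.60, 7.13]) of the AGM pre-HSC/endothelial library. The AGM pre-HSC/endothelial library held no macrophage-monocyte-like, lymphoid-like or cluster 8 cells, which allows up to 1.38% of each, although with 3000 variable genes and 20 components a cluster led by cluster 8 genes held 5 of its cells (2.30%). The gates set these shares in part, since the AGM gates asked for different CD45 levels and removed lineage-positive cells, while the fetal liver gate is given without lineage markers. Scrublet called 13 doublets, 4, 1 and 8 per library, which were kept.

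**Figure D1:**
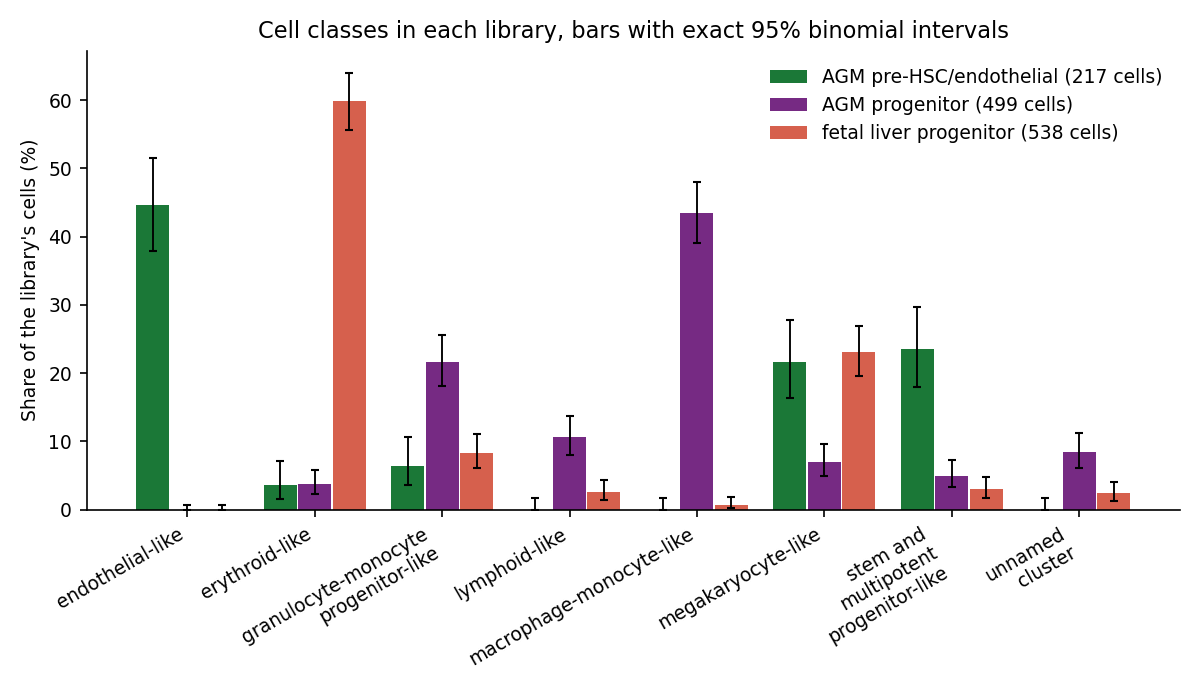
Share of the cells of each library (percent, bars from 0) in each cluster class, with exact 95% binomial intervals as error bars. Endothelial-like cells appear in the AGM pre-HSC/endothelial library alone (44.7%), macrophage-monocyte-like cells are the largest class of the AGM progenitor library (43.5%) and erythroid-like cells that of the fetal liver library (59.9%).

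Kit RNA was uneven within the AGM progenitor library, although all its cells were sorted as cKit+. It stood at 139 CPM [113, 169] in stem and multipotent progenitor-like cells and 81.5 CPM [71.2, 92.8] in the granulocyte-monocyte progenitor-like cluster 3. In the macrophage-monocyte-like clusters 7 and 9 it stood at 2.65 CPM [0.974, 5.77] and 6.79 CPM [1.85, 17.4], and in the macrophage-monocyte-like cluster 10 at 42.3 CPM [35.1, 50.6]. Of the 70 cells of cluster 10, 20 held both Xist and Y-linked UMIs, a combination that 1 male or female cell should lack.

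**Figure D2:**
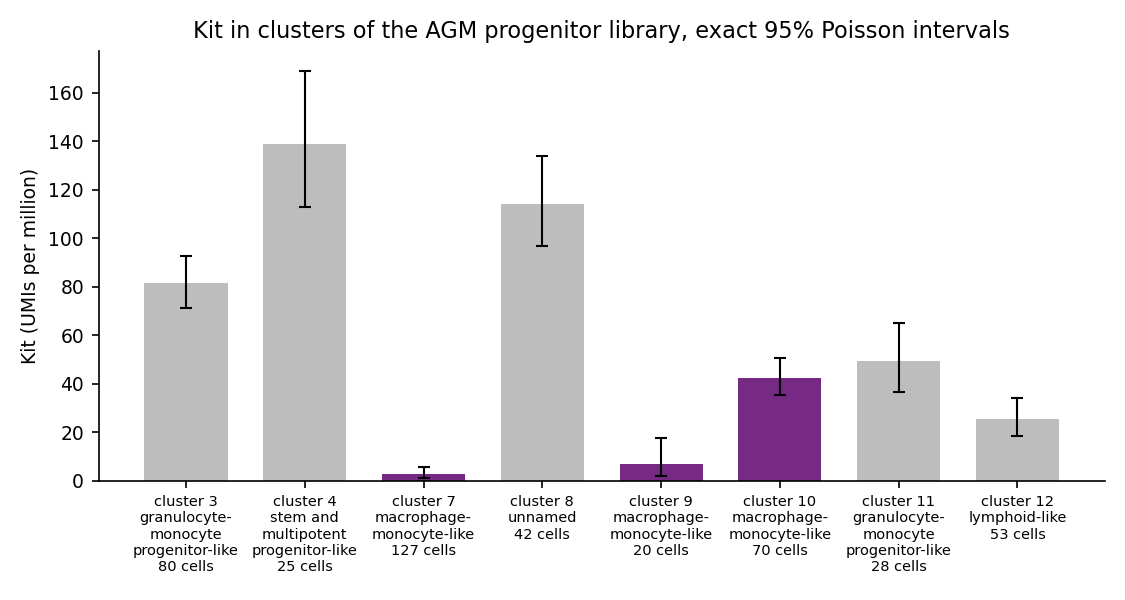
Kit (CPM, bars from 0) in each cluster with at least 20 cells in the AGM progenitor library, with exact 95% Poisson intervals as error bars. Purple bars are macrophage-monocyte-like clusters, where clusters 7 and 9 stand at 2.65 and 6.79 CPM and cluster 10 at 42.3 CPM, and gray bars are the other clusters, which range from 25.4 to 139 CPM.

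The first comparison set AGM cells of the pre-HSC and endothelial gate against AGM progenitors. The AGM pre-HSC/endothelial library was higher in endothelial and Hox genes, and the AGM progenitor library in macrophage, granulocyte-monocyte and mast cell genes. Cldn5, a tight junction protein of endothelium, stood at 184 CPM [174, 195] in the AGM pre-HSC/endothelial library and 0.334 CPM [0.108, 0.779] in the AGM progenitor library, a ratio of 552-fold [236, 1704]. C1qb, a subunit of complement C1q made by macrophages, had 0 UMIs in the AGM pre-HSC/endothelial library and 615 CPM [602, 627] in the AGM progenitor library, at least 1383-fold higher there. The genes are Cldn5 (ENSMUSG00000041378, chromosome 16, 18776847 to 18778262) and C1qb (ENSMUSG00000036905, chromosome 4, 136880129 to 136886187). Each further gene has its UMIs in the order of the comparison, then its CPM ratio.

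The pan-endothelial list was higher in the AGM pre-HSC/endothelial library (median log2 ratio 4.77 [2.92, 5.70], percentile 100, with 23 of 24 measured members at least 2-fold higher, 0 at least 2-fold lower and 1 between). The percentile places the median among those of 10000 random gene lists matched on expression. The other lists are described alike and called higher or lower by their medians. Besides Cldn5, its largest ratios were Clec14a (214 against 0 UMIs, at least 158-fold), a lectin of endothelial junctions, Emcn (1866 against 27 UMIs, 153-fold [105, 233]), the sialomucin endomucin, and Plvap (850 against 26 UMIs, 72.5-fold [49.1, 112]), a protein of endothelial fenestrae. The arterial list was higher (median 3.96 [0.31, 5.65], percentile 100, 11 measured, 9 higher, 0 lower, 2 between). Sox17 (229 against 1 UMI, 508-fold [90.3, 20150]) is a transcription factor of arterial and hemogenic endothelium and Efnb2 (39 against 3 UMIs, 28.8-fold [9.17, 146]) an arterial ephrin. Edn1 (68 against 1 UMI, 151-fold [26.2, 6044]) and Unc5b (32 against 1 UMI, 71.0-fold [11.9, 2890]) were the other leading members. The venous list was higher by its median (median 4.96 [-2.25, 6.99], percentile 100, 9 measured, 6 higher, 3 lower, 0 between). Nr2f2 (212 against 3 UMIs, 157-fold [52.9, 766]), the factor that sets venous identity, and Aplnr (230 against 4 UMIs, 128-fold [49.1, 472]) led it. Ephb4 (101 against 0 UMIs, at least 74.7-fold) and Flt4 (89 against 1 UMI, 197-fold [34.5, 7884]) followed. Its 3 lower members Dab2, Stab1 and Lyve1 are also genes of macrophages. Further genes among the 10 highest were Mest (3026 against 30 UMIs, 224-fold [156, 332]), an imprinted gene, and Cda (297 against 1 UMI, 659-fold [117, 26108]), cytidine deaminase. Fxyd6 (241 against 2 UMIs, 267-fold [73.2, 2220]), a regulator of the sodium pump, and Ly6h (214 against 3 UMIs, 158-fold [53.4, 773]) were there too. Mesenchyme markers were higher as well (list median 4.33), and 8 endothelial-like cells held at least 4 of them. Most Acta2 and Tagln UMIs lay in stem and multipotent progenitor-like cells.

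The Hox list was higher in every measured member (median 4.21 [3.02, 4.52], percentile 100, 15 measured, 15 higher, 0 lower, 0 between). Hoxb8 (68 against 1 UMI, 151-fold [26.2, 6044]), Hoxb7 (83 against 2 UMIs, 92.1-fold [24.7, 773]), Hoxa4 (31 against 2 UMIs, 34.4-fold [8.75, 296]) and Hoxd8 (31 against 0 UMIs, at least 22.9-fold) led it. The HSC-associated list was higher by its median (median 1.02 [0.44, 2.18], percentile 100, 25 measured, 13 higher, 2 lower, 10 between). Tcf15 (361 against 12 UMIs, 66.7-fold [37.7, 130.4]) and Hoxa5 (87 against 19 UMIs, 10.2-fold [6.13, 17.7]) were higher, as was Procr (96 against 37 UMIs, 5.76-fold [3.90, 8.65]), the endothelial protein C receptor found on stem cells. Gpr183 (53 against 739 UMIs, 6.29-fold [4.75, 8.47]), an oxysterol receptor, was lower. The fetal Lin28b list was higher by its median (median 0.57 [-0.60, 3.58], percentile 100, 13 measured, 6 higher, 1 lower, 6 between). Mest led it, with the imprinted genes Peg3 (502 against 39 UMIs, 28.6-fold [20.6, 40.6]), Igf2 (1008 against 187 UMIs, 12.0-fold [10.2, 14.1]) and H19 (803 against 234 UMIs, 7.61-fold [6.57, 8.84]). The Notch list was mixed (median 0.83 [-1.77, 2.61], percentile 99.3, 11 measured, 5 higher, 3 lower, 3 between). Dll4 (21 against 0 UMIs, at least 15.5-fold), an arterial ligand, Notch4 (22 against 8 UMIs, 6.10-fold [2.62, 15.8]) and Nrarp (79 against 36 UMIs, 4.87-fold [3.24, 7.43]) were higher. Dtx4 (4 against 96 UMIs, 10.8-fold [4.09, 40.5]) was lower. The BMP-TGFb list was higher by its median (median 0.24 [0.06, 2.19], percentile 97.0, 16 measured, 5 higher, 0 lower, 11 between). Bmp4 (78 against 6 UMIs, 28.8-fold [12.7, 81.0]), a ligand, and Id3 (1678 against 333 UMIs, 11.2-fold [9.93, 12.6]), a target of BMP signals, were higher. Ltbp1 (23 against 8 UMIs, 6.38-fold [2.75, 16.5]) and Eng (257 against 125 UMIs, 4.56-fold [3.67, 5.69]) were higher as well. The megakaryocyte list was higher (median 1.64 [0.88, 2.5], percentile 100, 19 measured, 13 higher, 1 lower, 5 between). Vwf (46 against 4 UMIs, 25.5-fold [9.31, 97.6]), which endothelium also makes, and F2r (340 against 116 UMIs, 6.50-fold [5.25, 8.10]), the thrombin receptor, led it. Mmrn1 (245 against 85 UMIs, 6.39-fold [4.98, 8.28]) and Rab27b (188 against 69 UMIs, 6.04-fold [4.56, 8.08]) followed.

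Genes of differentiated myeloid cells were lower in the AGM pre-HSC/endothelial library. The macrophage-monocyte list was lower (median -5.57 [-8.35, -3.09], percentile 0, 19 measured, 0 higher, 18 lower, 1 between). Beside C1qb stood the C1q genes C1qc (0 against 4087 UMIs, at least 614-fold) and C1qa (0 against 2885 UMIs, at least 434-fold) and Cx3cr1 (2 against 2214 UMIs, 499-fold [138, 4123]), the fractalkine receptor. Other genes among the 10 lowest were Mrc1 (3 against 2167 UMIs, 326-fold [111, 1580]), the mannose receptor, and Csf1r (2 against 1619 UMIs, 365-fold [101, 3016]), the receptor that macrophages need to survive. Ms4a6c (3 against 1701 UMIs, 256-fold [87.3, 1241]), Aif1 (0 against 1473 UMIs, at least 221-fold), Ly86 (0 against 1364 UMIs, at least 205-fold) and Trem2 (0 against 1153 UMIs, at least 173-fold) completed them. The granulocyte-monocyte progenitor list was lower (median -3.24 [-4.45, -1.29], percentile 0, 20 measured, 0 higher, 18 lower, 2 between). Elane (0 against 804 UMIs, at least 121-fold), neutrophil elastase, Igsf6 (5 against 759 UMIs, 68.4-fold [29.2, 211]) and Cebpe (0 against 427 UMIs, at least 64.2-fold) stood lowest besides Csf1r. The mast, basophil and eosinophil list was lower (median -2.96 [-4.78, -1.73], percentile 0, 11 measured, 0 higher, 10 lower, 1 between). Hdc (4 against 892 UMIs, 101-fold [39.1, 369.8]), which makes histamine, was lower. So were the eosinophil granule genes Prg3 (0 against 183 UMIs, at least 27.5-fold), Prg2 (0 against 173 UMIs, at least 26.0-fold) and Epx (0 against 64 UMIs, at least 9.62-fold), of which 5 cells held 176, 167 and 54 UMIs. Embryonic globins were lower too (median -8.48 [-8.64, -2.54], percentile 0, 3 measured, 0 higher, 3 lower, 0 between). They are Hba-x (6 against 5326 UMIs, 400.2-fold [184, 1091]), Hbb-y (12 against 9531 UMIs, 358-fold [205, 693]) and Hbb-bh1 (87 against 1120 UMIs, 5.80-fold [4.66, 7.30]). Adult globins were lower by their median (median -3.91 [-5.87, 1.17], percentile 0, 4 measured, 1 higher, 3 lower, 0 between). Hba-a2 (6 against 780 UMIs, 58.6-fold [26.8, 160.2]), Hba-a1 (14 against 1664 UMIs, 53.6-fold [31.8, 98.2]) and Hbb-bt (47 against 442 UMIs, 4.24-fold [3.13, 5.86]) were lower, whereas Hbb-bs (473 against 466 UMIs, 2.25-fold [1.98, 2.56]) was higher. The copies Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are near-identical, so the split of reads within each pair is uncertain. In the AGM progenitor library 9 cells held 15820 of the 15977 embryonic globin UMIs, and without cells of over 50 such UMIs the embryonic median was -1.13 and the log2 ratio of Hbb-bh1 reversed to 0.75. Hbb-bs had 250 of its 473 UMIs in 1 cell of the AGM pre-HSC/endothelial library and a log2 ratio that reversed to -0.89 without the 5% of cells with the most UMIs.

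The other lists of this comparison are given by their medians alone. Medians of lineage and division lists were 0.04 for hematopoietic transcription factors, 0.16 for erythroid, 0.29 for lymphoid, -0.04 for S phase and -0.12 for G2-M phase. Those of signalling and response lists were -0.24 for quiescence and CDK inhibitors, -0.70 for interferon and inflammatory, 1.65 for shear-responsive, 0.01 for adhesion and homing and 0.05 for dissociation immediate-early. Those of metabolic lists were -0.13 for glycolysis, 0.16 for oxidative phosphorylation, 0.41 for cholesterol synthesis and -0.0018 for heme synthesis and iron. The median of the 11610 genes measured was 0.01.

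Both AGM libraries held at least 20 megakaryocyte-like and at least 20 stem and multipotent progenitor-like cells. In megakaryocyte-like cells (47 against 35), the AGM pre-HSC/endothelial cells held more Cd34 (5.84-fold [3.28, 11.3]), a marker of the stem cell class, and Cela1 (8.46-fold [3.44, 26.9]). Tpm4 (5.47-fold [3.07, 10.6]), a tropomyosin, and Slc35d3 (4.70-fold [2.49, 9.80]), which platelet dense granules need, were higher as well. The same cells held less Dqx1 (10.4-fold [4.70, 27.3]), Lmo4 (8.47-fold [6.42, 11.3]), a transcription cofactor, Mpo (3.74-fold [2.98, 4.73]), a marker of the granulocyte-monocyte class, and Vim (3.41-fold [2.92, 4.00]), vimentin. Spns3 (7.18-fold [3.71, 15.2]), Ramp1 (4.84-fold [2.72, 9.08]), Arntl (3.82-fold [2.10, 7.29]) and Emc9 (3.41-fold [2.21, 5.38]) were lower too. Pf4, Clec1b and Rab27b are markers of the class and Mrvi1 is a leading gene of cluster 2, so their higher values are not counted. Clusters 0 and 2 held 14 and 33 of the AGM pre-HSC/endothelial cells and 16 and 19 of the AGM progenitor cells. Of the sort markers, Ptprc (4.84-fold [2.13, 12.4]) and Gypa (3.48-fold [1.25, 11]) were lower. The G2-M list, of genes for mitosis, was lower (median -0.18 [-0.35, -0.12], percentile 0.01, 48 measured, 0 higher, 0 lower, 48 between), with a median of -0.11 under median-of-ratios scaling. Ttk (1.71-fold [1.05, 2.79]), Gtse1 (1.68-fold [0.924, 3.09]), Ckap2 (1.52-fold [0.978, 2.38]) and Ndc80 (1.49-fold [1.05, 2.11]) had its largest ratios. The other medians were 0.33 for HSC-associated, -0.18 for hematopoietic transcription factors, 0.09 for S phase and 0.15 for oxidative phosphorylation. With all deposited barcodes, the stricter cell filter or resolution 1.5, under 20 such cells remained in a library and no value could be given.

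In stem and multipotent progenitor-like cells (51 against 25, all in cluster 4), the AGM pre-HSC/endothelial cells held more Acta2 (87 against 1 UMI, 37.5-fold [6.56, 1499]), smooth muscle actin and a mesenchyme marker that was higher together with Tagln (47 against 0 UMIs, at least 6.76-fold). Id3 (78 against 4 UMIs, 8.41-fold [3.16, 31.6]), Mt1 (47 against 6 UMIs, 3.38-fold [1.44, 9.67]), a metallothionein, and Jun (67 against 10 UMIs, 2.89-fold [1.48, 6.30]), an immediate-early factor, were higher. Kifap3 (3.45-fold [1.48, 9.87]), Ptms (3.16-fold [1.34, 9.09]) and Exoc4 (2.77-fold [1.24, 7.29]) were also higher, and Fam181b met the rule but is a leading gene of the cluster. Lower genes were Plac8 (3.90-fold [2.24, 6.94]), a marker of the granulocyte-monocyte class, Mob3a (2.74-fold [1.68, 4.49]) and Ep300 (2.19-fold [1.33, 3.60]), a histone acetyltransferase. Arf3 (2.24-fold [1.30, 3.86]), Hltf (2.24-fold [1.28, 3.90]), Haus7 (2.15-fold [1.19, 3.84]), Sumf2 (2.12-fold [1.28, 3.51]) and Golga3 (2.12-fold [1.37, 3.28]) were lower too. Of the sort markers, Cdh5 (56 against 9 UMIs, 2.68-fold [1.32, 6.17]) was higher and Ptprc (32 against 38 UMIs, 2.75-fold [1.67, 4.55]) lower. The G2-M list was lower (median -0.22 [-0.34, -0.12], percentile 0, 48 measured, 0 higher, 0 lower, 48 between). Psrc1 (1.99-fold [0.998, 3.92]), Nusap1 (1.74-fold [1.33, 2.28]), Ndc80 (1.69-fold [1.09, 2.58]) and Dlgap5 (1.66-fold [1.07, 2.66]) had its largest ratios, and of these Dlgap5 alone was higher. The other medians were -0.09 for hematopoietic transcription factors, 0.07 for S phase and 0.17 for oxidative phosphorylation. With all deposited barcodes the log2 ratio of Mt1 reversed to -0.34, and with cells thinned to 5000 UMIs that of Nusap1 reversed to 0.53. Of the 51 AGM pre-HSC/endothelial cells, 1 held germ cell markers.

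The second comparison set the progenitors of the fetal liver against those of the AGM. The fetal liver library was higher in erythroid genes, and the AGM progenitor library in macrophage, granulocyte-monocyte and mast cell genes. Slc30a10, a manganese transporter, stood at 9.61 CPM [8.29, 11.1] in the fetal liver library and 0.401 CPM [0.147, 0.872] in the AGM progenitor library, a ratio of 24.0-fold [10.8, 66.1]. Ccl24, a chemokine that attracts eosinophils, had 0 UMIs in the fetal liver library and 26.7 CPM [24.2, 29.5] in the AGM progenitor library, at least 175-fold higher there. The genes are Slc30a10 (ENSMUSG00000026614, chromosome 1, 185454848 to 185468762) and Ccl24 (ENSMUSG00000004814, chromosome 5, 135569937 to 135573049). The median of the 11610 genes measured was -0.10, or -0.05 under median-of-ratios scaling, and the medians of lists are read against that shift.

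The erythroid list was higher in the fetal liver (median 2.30 [1.73, 2.88], percentile 100, 21 measured, 18 higher, 0 lower, 3 between). Ermap (1417 against 81 UMIs, 13.3-fold [10.6, 16.9]), an erythroid membrane protein, and Tspo2 (312 against 20 UMIs, 11.9-fold [7.56, 19.7]), a sterol-binding protein of erythroid cells, led it. Sphk1 (123 against 8 UMIs, 11.7-fold [5.76, 27.7]), sphingosine kinase, and Car1 (1298 against 103 UMIs, 9.59-fold [7.84, 11.8]), carbonic anhydrase, followed. The heme and iron list was higher (median 0.89 [0.13, 1.43], percentile 100, 18 measured, 7 higher, 2 lower, 9 between). Cpox (5150 against 613 UMIs, 6.39-fold [5.88, 6.96]) and Alad (3499 against 657 UMIs, 4.05-fold [3.73, 4.41]) are enzymes of heme synthesis. Steap3 (1028 against 180 UMIs, 4.35-fold [3.71, 5.12]) is a ferrireductase and Slc11a2 (387 against 109 UMIs, 2.70-fold [2.18, 3.37]) an iron transporter. Other genes among the 10 highest were Pklr (188 against 10 UMIs, 14.3-fold [7.61, 30.3]), the pyruvate kinase of liver and red cells, and Ass1 (661 against 35 UMIs, 14.4-fold [10.2, 20.8]), an enzyme of arginine synthesis. Slc38a5 (767 against 45 UMIs, 13-fold [9.60, 17.9]), an amino acid transporter, Ndufa4l2 (120 against 4 UMIs, 22.8-fold [8.69, 85.2]), Nxpe2 (156 against 9 UMIs, 13.2-fold [6.77, 29.4]) and Crip2 (445 against 27 UMIs, 12.5-fold [8.50, 19.2]) were among them. So were Asb17 (320 against 17 UMIs, 14.3-fold [8.81, 24.9]) and Asb17os (102 against 6 UMIs, 12.9-fold [5.74, 36.1]), and a gene and its antisense neighbour cannot be told apart without strand. The megakaryocyte list was higher by its median (median 0.61 [-0.20, 1.54], percentile 100, 19 measured, 8 higher, 2 lower, 9 between). Gp5 (262 against 44 UMIs, 4.53-fold [3.28, 6.39]), a platelet glycoprotein, Rab27b (338 against 69 UMIs, 3.73-fold [2.87, 4.90]) and F2r (536 against 116 UMIs, 3.52-fold [2.87, 4.34]) were higher. Pf4 (276 against 1255 UMIs, 5.97-fold [5.24, 6.83]), platelet factor 4, was lower. Pf4 is also a marker of the macrophage-monocyte-like clusters 7 and 9. The mix of sorted CD41- and CD41high cells could not be separated from these values.

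Macrophage genes were lower in the fetal liver. The macrophage-monocyte list was lower in every measured member (median -5.12 [-5.95, -4.13], percentile 0, 19 measured, 0 higher, 19 lower, 0 between). Mrc1 (26 against 2167 UMIs, 109.5-fold [74.5, 168]), C1qa (45 against 2885 UMIs, 84.2-fold [62.8, 116]), C1qb (181 against 9203 UMIs, 66.8-fold [57.7, 77.8]) and Adgre1 (7 against 351 UMIs, 65.9-fold [31.6, 165]) stood lowest, the last encoding F4/80. Other genes among the 10 lowest were Stab1 (13 against 1523 UMIs, 154-fold [89.8, 289.8]) and Dab2 (51 against 3619 UMIs, 93.2-fold [70.8, 125]), which serve uptake of ligands, and Gas6 (4 against 372 UMIs, 122-fold [47.3, 451]), a bridge to dying cells. Mpeg1 (4 against 339 UMIs, 111-fold [43.1, 411]), perforin-2, Ctsh (2 against 243 UMIs, 159.7-fold [43.7, 1326]), a cathepsin, and Ccl2 (1 against 233 UMIs, 306-fold [54.4, 12144]), a monocyte chemokine, were among them. So were C3ar1 (8 against 585 UMIs, 96.1-fold [48.4, 224]), the C3a receptor, and Ednrb (10 against 719 UMIs, 94.5-fold [51.1, 198]). The granulocyte-monocyte progenitor list was lower (median -2.48 [-3.33, -2.13], percentile 0, 20 measured, 0 higher, 19 lower, 1 between). Csf1r (61 against 1619 UMIs, 34.9-fold [27.0, 45.8]), Ctsg (2 against 31 UMIs, 20.4-fold [5.18, 176]), Clec12a (36 against 357 UMIs, 13-fold [9.24, 18.9]) and Fcgr3 (249 against 2363 UMIs, 12.5-fold [10.9, 14.3]) stood lowest. The mast, basophil and eosinophil list was lower (median -3.27 [-6.24, -1.63], percentile 0, 11 measured, 0 higher, 11 lower, 0 between). Prg2 (1 against 173 UMIs, 227-fold [40.3, 9030]), Prg3 (2 against 183 UMIs, 120.2-fold [32.8, 1000]), Ms4a2 (1 against 45 UMIs, 59.1-fold [10.1, 2387]) and Epx (0 against 64 UMIs, at least 28.0-fold) stood lowest, with the granule genes again from 5 cells. The lymphoid list was lower (median -1.74 [-2.26, 0.54], percentile 0, 16 measured, 1 higher, 11 lower, 4 between). Blnk (3 against 39 UMIs, 17.1-fold [5.43, 86.4]), a B-cell linker, Lsp1 (263 against 1348 UMIs, 6.74-fold [5.90, 7.72]), Il7r (22 against 104 UMIs, 6.21-fold [3.89, 10.3]), the interleukin-7 receptor, and Id2 (64 against 233 UMIs, 4.78-fold [3.61, 6.41]) stood lowest. The HSC-associated list was lower (median -1.27 [-1.86, -0.38], percentile 0, 25 measured, 1 higher, 14 lower, 10 between). Gpr183 (61 against 739 UMIs, 15.9-fold [12.3, 21]), Mecom (4 against 25 UMIs, 8.21-fold [2.84, 32.5]), Hoxa9 (39 against 198 UMIs, 6.67-fold [4.71, 9.66]) and Hoxa5 (4 against 19 UMIs, 6.24-fold [2.07, 25.2]) stood lowest. The interferon and inflammatory list was lower (median -1.20 [-1.97, -0.64], percentile 0, 22 measured, 0 higher, 13 lower, 9 between). Irf7 (6 against 29 UMIs, 6.35-fold [2.59, 18.7]), Ifitm3 (273 against 1285 UMIs, 6.19-fold [5.42, 7.07]), Il6st (35 against 146 UMIs, 5.48-fold [3.77, 8.17]) and Irf1 (41 against 124 UMIs, 3.97-fold [2.77, 5.80]) stood lowest.

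Globin ratios between these libraries rested on few cells. The embryonic list was lower in the fetal liver by its median (median -0.74 [-1.0, -0.15], percentile 1.05, 3 measured, 0 higher, 0 lower, 3 between). Hbb-y (6270 against 9531 UMIs, 2.00-fold [1.93, 2.06]), Hba-x (4196 against 5326 UMIs, 1.67-fold [1.60, 1.74]) and Hbb-bh1 (1327 against 1120 UMIs, 1.11-fold [1.02, 1.20]) make it up. In the fetal liver library 1 cell held 6231 of the 6270 Hbb-y UMIs. The adult list was mixed (median 0.25 [-0.48, 2.64], percentile 85.2, 4 measured, 1 higher, 0 lower, 3 between). Hbb-bs (3813 against 466 UMIs, 6.23-fold [5.65, 6.87]) and Hbb-bt (962 against 442 UMIs, 1.66-fold [1.48, 1.86]) were higher, and Hba-a1 (1867 against 1664 UMIs, 1.17-fold [1.10, 1.25]) and Hba-a2 (737 against 780 UMIs, 1.39-fold [1.26, 1.54]) were lower. With at least 2000 genes and at most 5% mitochondrial UMIs the embryonic median was 1.40, and the log2 ratios of Hba-a1 and Hba-a2 reversed to 1.63 and 1.34. Without cells with over 50 embryonic globin UMIs the log2 ratios of Hbb-bh1, Hba-a1 and Hba-a2 were 2.85, 2.72 and 1.75. The embryonic median was -1.63 by the mean of per-cell CPM and -1.66 with cells thinned to 5000 UMIs. The log2 ratio of Hbb-bt reversed to -0.45 with cells thinned to 5000 UMIs, where the adult median was -0.90.

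For fetal liver over AGM progenitor, the remaining lists are also given by their medians alone. Those of endothelial, stem cell and patterning lists were -1.19 for pan-endothelial, -1.92 for arterial, -6.76 for venous, -0.90 for hematopoietic transcription factors, -1.62 for Hox and -0.86 for fetal Lin28b. The measured venous genes here were Stab1, Lyve1, Dab2 and Nrp2, which macrophages also express in part. Those of division, signalling and response lists were 0.22 for S phase, -0.36 for G2-M phase, -0.94 for quiescence and CDK inhibitors, -1.05 for Notch, -1.15 for BMP-TGFb, -2.82 for shear-responsive, -0.63 for adhesion and homing and -0.68 for dissociation immediate-early. Those of metabolic lists were 0.18 for glycolysis, 0.14 for oxidative phosphorylation and -0.34 for cholesterol synthesis.

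Within granulocyte-monocyte progenitor-like cells (45 fetal liver against 108 AGM), the G2-M list was lower in the fetal liver (median -0.58 [-0.78, -0.33], percentile 0, 48 measured, 0 higher, 7 lower, 41 between). Ckap2l (24 against 156 UMIs, 2.43-fold [1.57, 3.90]), Psrc1 (5 against 32 UMIs, 2.39-fold [0.924, 7.86]), Kif2c (15 against 94 UMIs, 2.34-fold [1.35, 4.35]) and Nusap1 (59 against 335 UMIs, 2.12-fold [1.60, 2.85]), which encode spindle and kinetochore proteins, had its largest ratios. Higher genes included Clec1b (52 against 34 UMIs, 4.09-fold [2.61, 6.51]) and Gng11 (75 against 60 UMIs, 3.35-fold [2.35, 4.78]), markers of the megakaryocyte class, Car2 (156 against 140 UMIs, 2.98-fold [2.36, 3.78]), a marker of the erythroid class, and Adgrl4 (2.47-fold [1.36, 4.48]), a marker of the stem cell class. Jun (2.71-fold [1.95, 3.77]), Homer2 (2.5-fold [1.44, 4.33]), Hpgd (2.45-fold [1.48, 4.05]) and Hist1h2bm (2.39-fold [1.59, 3.57]) were also higher, the last being 1 of many near-identical histone genes. Lower genes were Rnase12 (1 against 54 UMIs, 20.2-fold [3.47, 811]), a leading gene of cluster 8, and Rnaset2b (6 against 67 UMIs, 4.17-fold [1.82, 11.8]), which has a near-identical copy. Lsp1 (3.62-fold [1.89, 7.79]), Wrnip1 (3.36-fold [1.62, 8.08]), Flot2 (3.25-fold [1.49, 8.44]), Etl4 (3.15-fold [1.44, 8.17]), Strip1 (3.11-fold [1.33, 8.88]) and Kmt2d (2.99-fold [1.36, 7.77]) were lower too. The other medians were 0.08 for HSC-associated, 0.08 for hematopoietic transcription factors, 0.15 for S phase and 0.09 for oxidative phosphorylation. Cluster 3 held 35 of the fetal liver and 80 of the AGM cells, and cluster 11 held 10 and 28.

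In megakaryocyte-like cells (124 fetal liver against 35 AGM), the fetal liver cells held more Phkg1 (139 against 2 UMIs, 21.1-fold [5.72, 176]), a phosphorylase kinase subunit, F10 (110 against 4 UMIs, 8.34-fold [3.17, 31.1]), coagulation factor X, P3h3 (5.15-fold [1.67, 25.8]) and Abcb4 (4.85-fold [1.80, 18.3]). They held less Dqx1 (7.35-fold [4.36, 12.8]), Cpa3 (3.85-fold [2.57, 5.78]), a marker of the mast cell class, Csf2rb (3.85-fold [2.15, 6.94]), a cytokine receptor chain, Fgf3 (2.92-fold [1.92, 4.42]), Siglecf (2.84-fold [1.60, 5.03]) and Slco3a1 (2.71-fold [1.49, 4.88]). The granulocyte-monocyte markers Nkg7 (2.76-fold [1.72, 4.40]) and Serpinb1a (2.66-fold [1.57, 4.46]) were lower too. Pf4 and Clec1b are markers of the class, and Tnni1 and Sardh are leading genes of its clusters, so they are not counted. The fetal liver cells lay mostly in cluster 0 (78, with 46 in cluster 2) and the AGM cells mostly in cluster 2 (19, with 16 in cluster 0). Of the sort markers, Ptprc (2.20-fold [1.29, 3.71]) and Pecam1 (1.71-fold [1.04, 2.75]) were lower. The G2-M list was lower (median -0.31 [-0.35, -0.17], percentile 0, 48 measured, 0 higher, 0 lower, 48 between). Nek2 (1.85-fold [1.26, 2.69]), Ect2 (1.63-fold [1.16, 2.28]), Kif11 (1.51-fold [1.26, 1.81]) and Gtse1 (1.48-fold [0.894, 2.39]) had its largest ratios. The other medians were -0.18 for HSC-associated, -0.31 for hematopoietic transcription factors, 0.07 for S phase and 0.10 for oxidative phosphorylation. At resolution 0.6 the G2-M median was -0.11, and under the settings that left under 20 AGM cells no value could be given.

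The third comparison set the AGM pre-HSC/endothelial library against fetal liver progenitors. The AGM library was higher in endothelial and Hox genes, and the fetal liver library in erythroid genes. Mest stood at 448 CPM [433, 465] in the AGM pre-HSC/endothelial library and 0.152 CPM [0.0314, 0.446] in the fetal liver library, a ratio of 2940-fold [1005, 14265] from 3026 against 3 UMIs. Hdc, histidine decarboxylase, was lower in the AGM library, at 0.593 CPM [0.161, 1.52] against 9.10 CPM [7.82, 10.5], or 15.4-fold [5.89, 57.0] lower. The genes are Mest (ENSMUSG00000051855, chromosome 6, 30723547 to 30748465) and Hdc (ENSMUSG00000027360, chromosome 2, 126593667 to 126619299).

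The pan-endothelial list was higher in the AGM library (median 5.48 [3.48, 6.19], percentile 100, 24 measured, 22 higher, 0 lower, 2 between). Cldn5 (1245 against 0 UMIs, at least 1210-fold), Emcn (1866 against 7 UMIs, 777-fold [376, 1935]), Clec14a (214 against 0 UMIs, at least 208-fold) and Ramp2 (2258 against 40 UMIs, 165-fold [120.5, 231]) led it. Other genes among the 10 highest were Col4a1 (900 against 5 UMIs, 525-fold [224, 1620]), a collagen of basement membranes, Serpinh1 (1491 against 15 UMIs, 289.7-fold [175, 519]), a collagen chaperone, and Ptn (270 against 0 UMIs, at least 262-fold), the growth factor pleiotrophin. Meg3 (303 against 2 UMIs, 442-fold [121, 3663]), an imprinted noncoding RNA, Gap43 (307 against 0 UMIs, at least 298-fold), S100a16 (683 against 0 UMIs, at least 664-fold) and Limch1 (243 against 2 UMIs, 354-fold [97.0, 2941]) were among them. The Hox list was higher in every measured member (median 4.82 [4.52, 5.60], percentile 100, 15 measured, 15 higher, 0 lower, 0 between). Hoxb7 (83 against 0 UMIs, at least 80.6-fold), Hoxb2 (50 against 2 UMIs, 72.9-fold [19.1, 618]), Hoxb8 (68 against 0 UMIs, at least 66.1-fold) and Hoxa5 (87 against 4 UMIs, 63.4-fold [23.9, 238]) led it. The HSC-associated list was higher (median 1.92 [1.09, 3.89], percentile 100, 25 measured, 19 higher, 1 lower, 5 between). Hoxa5, Tcf15 (361 against 17 UMIs, 61.9-fold [38.1, 107]), Mecom (51 against 4 UMIs, 37.2-fold [13.7, 142]) and Procr (96 against 8 UMIs, 35.0-fold [17.1, 83.3]) led it. The fetal Lin28b list was higher (median 1.31 [0.13, 5.58], percentile 100, 12 measured, 7 higher, 0 lower, 5 between). Mest, Igf2 (1008 against 38 UMIs, 77.3-fold [55.9, 109.9]), a growth factor, H19 (803 against 49 UMIs, 47.8-fold [35.8, 65.1]) and Peg3 (502 against 58 UMIs, 25.2-fold [19.2, 33.7]) led it. The list of quiescence genes and inhibitors of cyclin-dependent kinases was higher by its median (median 0.60 [-0.16, 1.37], percentile 97.8, 12 measured, 5 higher, 1 lower, 6 between). Cdkn1c (2083 against 204 UMIs, 29.8-fold [25.8, 34.5]), the kinase inhibitor p57, Btg1 (188 against 205 UMIs, 2.67-fold [2.18, 3.27]) and Btg2 (55 against 62 UMIs, 2.59-fold [1.77, 3.78]) were higher. Cdkn2c (3 against 37 UMIs, 4.23-fold [1.34, 21.4]) was lower.

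The erythroid list was lower in the AGM library (median -2.18 [-3.35, -1.45], percentile 0, 21 measured, 0 higher, 18 lower, 3 between). Sphk1 (1 against 123 UMIs, 42.2-fold [7.43, 1680]), Rhd (6 against 236 UMIs, 13.5-fold [6.11, 37.1]), the Rh antigen, Tspo2 (10 against 312 UMIs, 10.7-fold [5.74, 22.5]) and Cldn13 (6 against 187 UMIs, 10.7-fold [4.82, 29.5]), an erythroid claudin, stood lowest. The heme and iron list was lower (median -0.94 [-1.57, -0.46], percentile 0, 18 measured, 0 higher, 7 lower, 11 between). Cpox (391 against 5150 UMIs, 4.52-fold [4.08, 5.02]) and Steap3 (84 against 1028 UMIs, 4.20-fold [3.36, 5.31]) stood lowest. Alas2 (0 against 36 UMIs, at least 4.12-fold), the erythroid enzyme that starts heme synthesis, and Tfrc (138 against 1459 UMIs, 3.63-fold [3.04, 4.35]), the transferrin receptor, followed. Other genes among the 10 lowest were Mt2 (29 against 864 UMIs, 10.2-fold [7.07, 15.4]), a metallothionein, Mst1r (2 against 102 UMIs, 17.5-fold [4.72, 146]), a receptor kinase, Atp1b2 (7 against 277 UMIs, 13.6-fold [6.50, 34.1]), Fam46a (7 against 269 UMIs, 13.2-fold [6.31, 33.1]) and Slc45a3 (2 against 109 UMIs, 18.7-fold [5.05, 156]). Hdc, Fam46a and Slc45a3 are leading genes of the unnamed cluster 8, which held no cells of the AGM library at the main settings. The embryonic globins were lower (median -7.49 [-7.91, -2.39], percentile 0, 3 measured, 0 higher, 3 lower, 0 between). Hba-x (6 against 4196 UMIs, 239.9-fold [110.1, 654]), Hbb-y (12 against 6270 UMIs, 179-fold [103, 347]) and Hbb-bh1 (87 against 1327 UMIs, 5.23-fold [4.21, 6.58]) make up this list. Adult globins were lower as well (median -4.10 [-5.52, -1.47], percentile 0, 4 measured, 0 higher, 4 lower, 0 between). Hba-a1 (14 against 1867 UMIs, 45.8-fold [27.2, 83.8]), Hba-a2 (6 against 737 UMIs, 42.1-fold [19.3, 115]), Hbb-bt (47 against 962 UMIs, 7.02-fold [5.24, 9.62]) and Hbb-bs (473 against 3813 UMIs, 2.77-fold [2.51, 3.05]) are the members measured. Without the cells of over 50 embryonic globin UMIs the embryonic median was -1.22.

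For AGM pre-HSC/endothelial over fetal liver, the same holds for the remaining lists. Those of endothelial and lineage lists were 4.83 for arterial, 6.43 for venous, 0.45 for hematopoietic transcription factors, -0.73 for granulocyte-monocyte progenitor, -0.76 for macrophage-monocyte, 0.91 for megakaryocyte, -0.46 for mast-basophil-eosinophil and 1.08 for lymphoid. Those of division, signalling and response lists were -0.21 for S phase, 0.16 for G2-M phase, 2.08 for Notch, 1.54 for BMP-TGFb, 0.26 for interferon and inflammatory, 3.92 for shear-responsive, 0.50 for adhesion and homing and 0.69 for dissociation immediate-early. Those of metabolic lists were -0.28 for glycolysis, -0.06 for oxidative phosphorylation and 0.68 for cholesterol synthesis. The median of the 11433 genes measured was 0.08. With cells thinned to 5000 UMIs the megakaryocyte median was 0.34, and Ptprc, lower in the AGM library at a log2 ratio of -0.54, stood at 0.006.

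In megakaryocyte-like cells (47 AGM against 124 fetal liver), the AGM pre-HSC/endothelial cells held more Smagp (106 against 48 UMIs, 4.89-fold [3.45, 7.03]), Cd34 (113 against 53 UMIs, 4.72-fold [3.38, 6.67]), Gatm (4.43-fold [2.49, 8.13]), an enzyme of creatine synthesis, and Rbp1 (4.19-fold [2.77, 6.42]), a retinol-binding protein. Lyz2 (3.63-fold [2.36, 5.66]), a marker of the macrophage class, Ndn (3.62-fold [2.07, 6.47]), an imprinted gene, and Cables2 (2.90-fold [1.69, 5.03]) were higher as well. The same cells held less Lmo4 (60 against 698 UMIs, 5.25-fold [4.03, 6.96]), Anxa2 (5.17-fold [2.62, 11.6]), an annexin, and Phkg1 (4.83-fold [2.73, 9.30]). Palm (4.06-fold [1.62, 13.1]), Tnni3 (3.88-fold [2.01, 8.39]), Rec114 (3.53-fold [1.88, 7.34]) and H2-T23 (3.42-fold [1.55, 8.91]) were lower too. Tsix (5.24-fold [2.12, 16.7]) was lower too, but lies antisense to Xist, and H2-T23 belongs to a family of similar genes. Tmem163 is a leading gene of cluster 2 and is not counted, since 33 of the 47 AGM cells and 46 of the 124 fetal liver cells lay in that cluster. Of the sort markers, Ptprc (2.20-fold [1.01, 5.45]) and Gypa (3.09-fold [1.30, 8.89]) were lower and Cdh5 (6 against 1 UMI, 13.3-fold [1.61, 611]) higher. The G2-M list stood near 0 (median 0.01 [-0.05, 0.11], percentile 40.0, 48 measured, 0 higher, 0 lower, 48 between). Kif11 (1.35-fold [1.15, 1.59]), Nek2 (1.32-fold [0.909, 1.91]), Hjurp (1.27-fold [1.01, 1.59]) and Cdk1 (1.23-fold [1.11, 1.36]) had its largest ratios, all higher. The other medians were 0.47 for HSC-associated, -0.03 for hematopoietic transcription factors, -0.0040 for S phase and 0.08 for oxidative phosphorylation. With the stricter cell filter the G2-M median was -0.31, and the log2 ratios of Kif11 and Cdk1 reversed to -0.23 and -0.10.

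**Figure D3:**
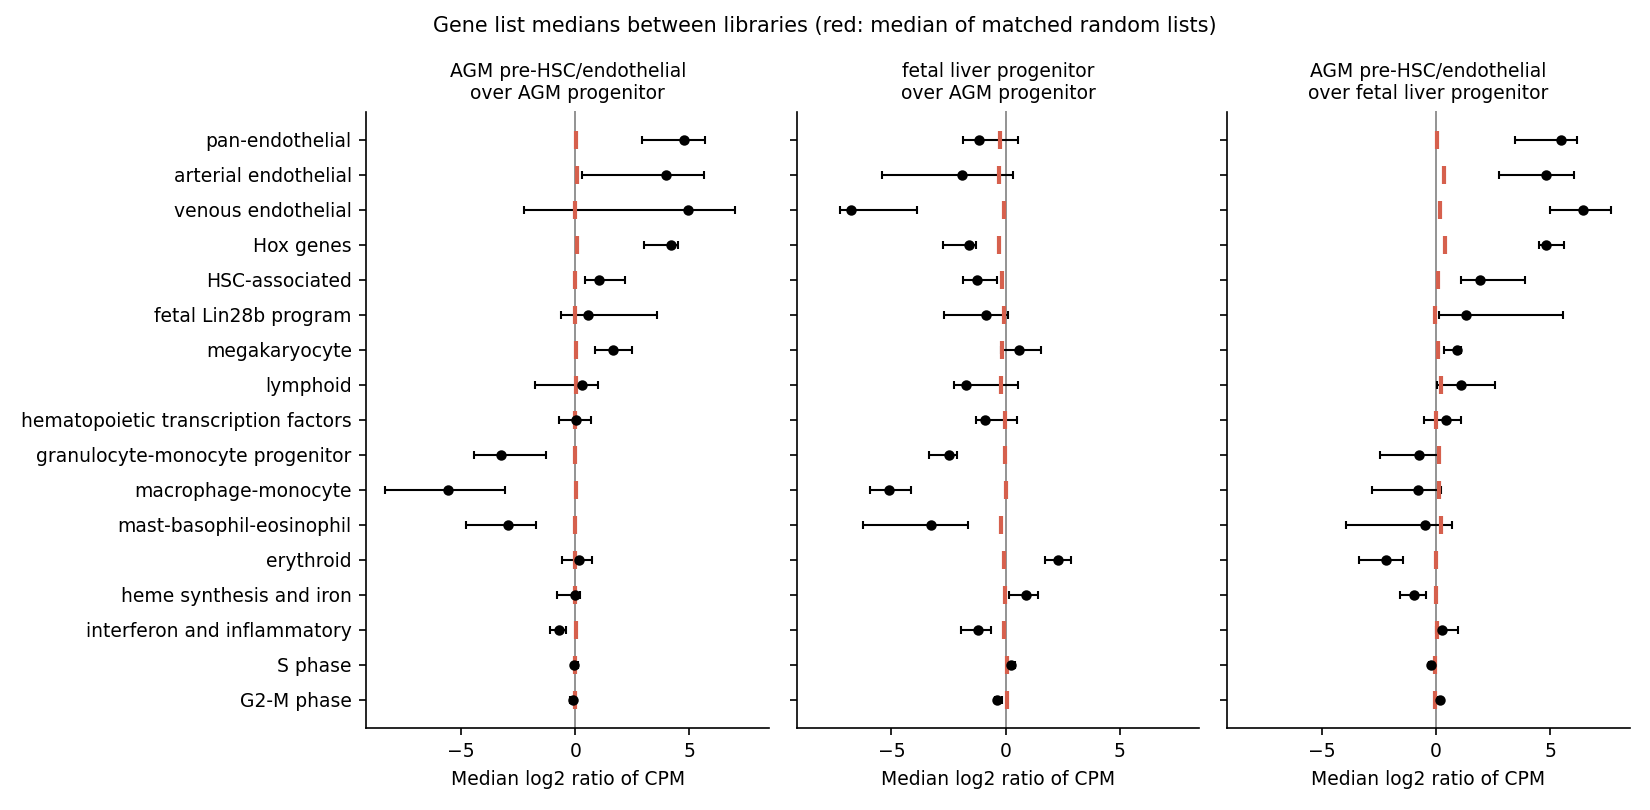
Median log2 ratio of CPM (x axis) of 17 fixed gene lists (rows) in the 3 comparisons of libraries, 1 panel each. Points are medians with 95% order-statistic intervals as error bars, and red ticks are medians of matched random lists. The pan-endothelial median stands at 4.77 and 5.48 in the panels for the AGM pre-HSC/endothelial library, and the macrophage-monocyte median at -5.57 and -5.12 in the panels against the AGM progenitor library.

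Proliferation genes were compared with every cell thinned to 5000 UMIs, which left out 6, 31 and 18 cells. Mki67, a protein of dividing cells, was detected in 42.7% [35.9, 49.6] of AGM pre-HSC/endothelial cells, 67.7% [63.3, 72.0] of AGM progenitor cells and 58.8% [54.5, 63.1] of fetal liver cells. Top2a, a topoisomerase of S and G2 phase, was detected in 60.7% [53.7, 67.3], 72.9% [68.6, 76.8] and 66.7% [62.5, 70.8]. Endothelial-like cells had the lowest Mki67 share, 21.3% [13.5, 30.9], at the same 5000 UMIs per cell, and no class of cells that lack Mki67 was at hand to set the background. At their own depth the shares were 73.3%, 89.8% and 92.4% for Mki67 and 87.1%, 88.8% and 95.5% for Top2a, an order that follows depth and differs from the thinned one. By summed counts Mki67 stood at 177 [167, 188], 293 [284, 301] and 224 [218, 231] CPM. The share called S or G2-M was 82.9% [77.2, 87.8], 93.2% [90.5, 95.3] and 97.5% [95.8, 98.7], and free RNA enters such calls, so no cycling was read from them.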

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

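The tests of free RNA for all 3 patterns, and the tests of droplets with 2 cells for the Xist and Kit patterns, were chosen only after the result was seen. The design gives no groups within 1 library, so no biological explanation was tested beyond RNA or cells of other kinds as the source.

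In the AGM progenitor library 25 cells held more than 1 Xist UMI and at least 1 Y-linked UMI, against 0 in the AGM pre-HSC/endothelial and 1 in the fetal liver library, and 23 of them were macrophage-monocyte-like. Free RNA of the other sex is argued against as the whole source, because 10.6% [6.84, 15.5] of macrophage-monocyte-like cells and 0.709% [0.0860, 2.54] of the other cells held both. Droplets with 2 cells stay open: 69.6% [47.1, 86.8] of the 23 held both at over 20% of the level of cells with 1 of them, median UMIs were 52822 against 22552 in the other macrophage-monocyte-like cells, and Scrublet called 0 of the 23. A first form of this test, the share above the median UMI count of the others, gave 23 of 23 and was replaced after that was seen, because holding both kinds of UMI selects for depth. Erythroid RNA taken up by macrophages stays open too, with an embryonic globin UMI in 13% (3 of 23) against 12.9% (25 of 194).

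In the same library 9 cells, 6 macrophage-monocyte-like and 3 erythroid-like, held 15820 of the 15977 embryonic globin UMIs. Free RNA of erythroid cells is argued against, since those 99% lie in so few cells. Droplets with 2 cells stay open: 22.2% [2.81, 60.0] of the 9 lay above the library's median of 30644 UMIs other than globins, but that bar was wrong, since a macrophage-monocyte-like cell of cluster 7 (median 17006) and an erythroid-like cell (9361) together stay below it. Erythroid cells that passed the sort stay open too: the erythroid list had a median log2 ratio of 1.85 [1.01, 3.38] in the 9 cells over the others (18 genes measured), but cells chosen for globins would show this in droplets with 2 cells as well, and 6 of the 9 are not erythroid-like.

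In the AGM progenitor library Kit stood lower in macrophage-monocyte-like cells than in the other cells. Lower depth is argued against, since at 5000 UMIs per cell 6.12% [3.20, 10.5] of them had a Kit UMI against 29.0% [23.7, 34.8] of the other cells. Free RNA as the only source of their Kit UMIs is argued against, because Kit stood at 42.3 CPM [35.1, 50.6] in cluster 10 and 2.65 CPM [0.974, 5.77] in cluster 7; a first form of this test, Kit at 30.1% [24.8, 36.3] of its level in the other cells against Myb at 24.4%, Cd34 at 42.0% and Mpo at 14.0%, had not decided it. Droplets of a macrophage and a second cell with Kit may add to it: 48.9% [33.7, 64.2] of the 45 macrophage-monocyte-like cells with a Kit UMI held Xist and Y-linked UMIs, near the 48.5% of mixed pairs at this split of sexes, against 0.581% [0.0147, 3.20] of the 172 without. Holding more UMIs favours both findings in a cell, so depth was not separated from that last share.

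Among the 32 genes named in megakaryocyte-like or stem and multipotent progenitor-like cells, 2 stood in opposite directions in these classes when AGM pre-HSC/endothelial was set over AGM progenitor. The log2 ratio of Mt1 was -0.21 [-0.39, -0.04] in megakaryocyte-like and 1.76 [0.53, 3.27] in stem and multipotent progenitor-like cells, and that of Vim was -1.77 [-2.00, -1.54] and 0.46 [0.13, 0.80]. With all deposited barcodes, which also changed the clusters, the second value of Mt1 was -0.34. Neither the cause nor these differences between classes were tested.

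The barcodes left out by the cell filter had a median mitochondrial share of 35.4% in the AGM pre-HSC/endothelial, 12.5% in the AGM progenitor and 66.7% in the fetal liver library.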

How the results depend on the processing

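The 5 settings that left out cells by the markers they held were chosen only after the result was seen. P1 stands for AGM pre-HSC/endothelial over AGM progenitor, P2 for fetal liver over AGM progenitor and P3 for AGM pre-HSC/endothelial over fetal liver, with any class named. Of 4111 log2 ratios of 323 results under the alternatives, 3798 stayed within the interval of the value reported, 291 moved beyond it and 22 reversed. Of 1901 list medians, 1854 stayed within the interval and 47 moved, and of 186 shares 113 stayed and 73 moved, of which those of the main results are given. Most of the 291 came from thinning (120), the stricter cell filter (60) and the mean of per-cell CPM (57). The cause was not tested where a value moved or reversed.

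The log2 ratios that reversed are these. Without cells with over 50 embryonic globin UMIs they were Hbb-bh1 0.75 (P1) and Hbb-bh1 2.85, Hba-a2 1.75 and Hba-a1 2.72 (P2). With the mean of per-cell CPM they were Hbb-bs -0.14 (P1) and Hbb-bt -0.36 (P2). Without the 5% of cells with the most UMIs they were Hbb-bs -0.89 (P1). With cells thinned to 5000 UMIs they were Hbb-bs -0.017 (P1), Hbb-bt -0.45 (P2), Ptprc 0.006 (P3) and Nusap1 0.53 (P1, stem-like). Without the cell with germ cell markers they were Pou5f1 -0.20 and Dnd1 -0.061 (P1). With at least 2000 genes and at most 5% mitochondrial UMIs they were Hbb-y 1.16, Hba-x 1.40, Hbb-bh1 1.98, Hba-a2 1.34 and Hba-a1 1.63 (P2) and Kif11 -0.23 and Cdk1 -0.097 (P3, megakaryocyte-like). With all deposited barcodes they were Mt1 -0.34 (P1, stem-like). At resolution 1.5 they were Cdk1 -0.016 (P3, megakaryocyte-like).

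The list medians that moved are these. Without cells with over 50 embryonic globin UMIs they were embryonic globins -1.13 (P1) and -1.22 (P3). With the mean of per-cell CPM they were embryonic globins -9.57, cholesterol synthesis 0.60 and Hox genes 4.80 (P1), granulocyte-monocyte -1.98, embryonic globins -1.63 and adult globins -0.81 (P2), S phase -0.33 and G2-M 0.035 (P3) and transcription factors -0.002 (P1, stem-like). With cells thinned to 5000 UMIs they were G2-M -0.23 and cholesterol synthesis 0.56 (P1), embryonic globins -1.66, adult globins -0.90, cholesterol synthesis -0.062 and epithelium 0.10 (P2), megakaryocyte 0.34, S phase -0.35, Hox genes 4.20, hepatoblast 4.30 and epithelium 0.52 (P3), S phase -0.047 (P1, megakaryocyte-like), S phase -0.14 (P1, stem-like), transcription factors 0.23 (P2, granulocyte-monocyte-like) and transcription factors -0.18 (P3, megakaryocyte-like). Without the cell with germ cell markers they were transcription factors -0.040 (P1, stem-like). With at least 2000 genes and at most 5% mitochondrial UMIs they were embryonic globins 1.40 (P2), embryonic globins -8.71, S phase -0.15 and Hox genes 4.48 (P3) and HSC-associated 0.27, transcription factors -0.24, S phase 0.10, G2-M -0.31 and oxidative phosphorylation 0.13 (P3, megakaryocyte-like). With no UMI minimum for list members they were Hox genes 4.22 (P3). With a pseudocount of 0.5 they were Hox genes 5.94 and mesenchyme 6.95 (P3). Without cells with at least 4 mesenchyme markers they were epithelium 0.80 (P3). Under median-of-ratios scaling they were S phase 0.16 and G2-M -0.11 (P1, megakaryocyte-like) and transcription factors -0.010 (P1, stem-like). With all deposited barcodes they were transcription factors -0.040 (P1, stem-like). At resolution 0.6 they were transcription factors -0.20 (P2, granulocyte-monocyte-like) and G2-M -0.11 (P2, megakaryocyte-like) and -0.052 (P3, megakaryocyte-like).

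The shares that moved are these, by library. With at least 2000 genes and at most 5% mitochondrial UMIs they were endothelial 31.3%, granulocyte-monocyte 11.7% and megakaryocyte 16.0% (AGM pre-HSC/endothelial), erythroid 1.97%, macrophage-monocyte 38.8% and megakaryocyte 4.42% (AGM progenitor) and erythroid 51.0% and megakaryocyte 8.33% (fetal liver). With all deposited barcodes they were endothelial 37.5%, granulocyte-monocyte 1.11% and megakaryocyte 6.32% (AGM pre-HSC/endothelial), megakaryocyte 0.173% (AGM progenitor) and granulocyte-monocyte 6.07%, megakaryocyte 4.51% and stem 5.89% (fetal liver). At resolution 0.6 they were granulocyte-monocyte 26.3% and megakaryocyte 11.2% (AGM progenitor) and erythroid 65.6% and megakaryocyte 19.5% (fetal liver). At resolution 1.5 they were granulocyte-monocyte 17.8% and megakaryocyte 2.20% (AGM progenitor) and erythroid 55.4% and megakaryocyte 11% (fetal liver). With 3000 variable genes and 20 components they were granulocyte-monocyte 0%, megakaryocyte 13.8% and stem 37.8% (AGM pre-HSC/endothelial), granulocyte-monocyte 14.8%, megakaryocyte 4.41% and stem 9.02% (AGM progenitor) and granulocyte-monocyte 3.72%, megakaryocyte 16.0% and stem 6.32% (fetal liver). Without the doublets called they were granulocyte-monocyte 3.29% (AGM pre-HSC/endothelial) and erythroid 54.5% and megakaryocyte 16.4% (fetal liver). Without cell cycle genes among the variable genes they were megakaryocyte 12.9% (AGM pre-HSC/endothelial), megakaryocyte 2.81% (AGM progenitor) and erythroid 54.5% and megakaryocyte 8.55% (fetal liver). At their own depth they were Mki67 73.3% and Top2a 87.1% (AGM pre-HSC/endothelial), Mki67 89.8% and Top2a 88.8% (AGM progenitor) and Mki67 92.4%, Top2a 95.5% and S or G2-M 98.9% (fetal liver). With cells thinned to 10000 UMIs they were Mki67 61.1%, Top2a 77.3% and S or G2-M 90.6% (AGM pre-HSC/endothelial), Mki67 82.2%, Top2a 87.3% and S or G2-M 95.6% (AGM progenitor) and Mki67 76.4%, Top2a 82.0% and S or G2-M 99.0% (fetal liver).

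Some class comparisons could not be given, because a library held under 20 cells. For megakaryocyte-like cells of P1 and P2 this held with all deposited barcodes (1 AGM progenitor cell), at least 2000 genes and at most 5% mitochondrial UMIs (18) and resolution 1.5 (11), and of P3 with all deposited barcodes (17 and 26 cells). Depth limits genes with few UMIs: 3 UMIs equal 0.445, 0.20 and 0.153 CPM in the 3 libraries, and with cells thinned to 5000 UMIs 188 log2 ratios could be given, of which 64 stayed, 120 moved and 4 reversed. No paired analysis was possible because each group has 1 library.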

Other observations

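The values without cells chosen by their markers were computed only after the result was seen. Mesenchyme markers stood higher in the AGM pre-HSC/endothelial library than in the AGM progenitor library (median 4.33 [3.29, 5.52], percentile 100, 10 measured, 9 higher, 0 lower, 1 between), led by Col3a1 (70 against 2 UMIs, 77.6-fold [20.7, 654]), Tagln (62 against 0 UMIs, at least 45.8-fold), Acta2 (119 against 7 UMIs, 37.7-fold [17.7, 95.8]) and Nr2f1 (45 against 2 UMIs, 49.9-fold [13, 425]). The 8 endothelial-like cells with at least 4 of these markers held 61 of the 70 Col3a1 UMIs, 27 of the 45 Nr2f1 UMIs, 23 of the 119 Acta2 UMIs and 11 of the 62 Tagln UMIs. Most Acta2 and Tagln UMIs of this library lay in its stem and multipotent progenitor-like cells. The same list had a median of 0.83 for fetal liver over AGM progenitor and 4.75 for AGM pre-HSC/endothelial over fetal liver.

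Germ cell markers also stood higher in the AGM pre-HSC/endothelial library than in the AGM progenitor library (median 1.40 [-1.69, 5.15], percentile 97.0, 5 measured, 3 higher, 1 lower, 1 between), with Dppa3 (48 against 3 UMIs, 35.5-fold [11.4, 178]), Pou5f1 (63 against 18 UMIs, 7.76-fold [4.54, 13.9]) and Dnd1 (25 against 21 UMIs, 2.64-fold [1.42, 4.96]), while Prdm1 (7 against 50 UMIs, 3.22-fold [1.45, 8.42]) was lower. In the stem and multipotent progenitor-like class 1 cell of 57868 UMIs held 7 of 10 germ cell markers, where the next highest cell held 2. It held 48 UMIs of Dppa3, 56 of Pou5f1, 40 of Epcam and 8 of Kit, and 0 of Ptprc, Cdh5 and Runx1. Without it, the log2 ratio of Pou5f1 was -0.20 and that of Dnd1 -0.06. The germ cell list had a median of -1.61 for fetal liver over AGM progenitor and 3.05 for AGM pre-HSC/endothelial over fetal liver.

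In the AGM progenitor library 5 granulocyte-monocyte progenitor-like cells held 167 of the 173 Prg2, 176 of the 183 Prg3 and 54 of the 64 Epx UMIs. The other lists of other cell types had 1 to 5 measured members, with medians of -0.06 for hepatoblast, 0.45 for epithelium, 0.89 for neural crest and neuron and -0.55 for muscle for AGM pre-HSC/endothelial over AGM progenitor. In the same order these were -1.05, -1.05, 0.48 and 0.07 for fetal liver over AGM progenitor. They were -0.14, 1.26, 0.41 and -0.63 for AGM pre-HSC/endothelial over fetal liver. With cells thinned to 5000 UMIs the last hepatoblast median was 4.30, and the epithelium medians were 0.10 for fetal liver over AGM progenitor and 0.52 for AGM pre-HSC/endothelial over fetal liver.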
